A study of Homo sapiens with 6 samples.

How the data were processed

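The samples were 6 preparations of total RNA from THLE 2 cells, 3 from untransfected cells and 3 from cells 48 h after transfection with FASN siRNA, per the labels. The labels' protocols name Trizol extraction, an RNeasy clean-up with DNase I, a Bioanalyzer check, biotinylated cRNA from an Ambion MessageAmp kit and Illumina HumanHT-12 V4.0 beadchips. Groups and replicate numbers were taken from the sample titles, and array columns were matched to samples by the codes in the sample descriptions.

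The deposited scanner table holds, per the file headers, the average bead intensity of each of 47316 probes on each array, on a linear scale. Its values were at least 18.8 on every array and their medians differed between arrays, from 40.2 to 53.0, so they were taken as neither background-subtracted nor normalized. The same deposited table gives a detection p-value per probe and array, per the file headers; it moves in steps of 1 in 770, which implies 770 negative control probes. The authors also deposited a second table of log2 values whose processing is not given in the sources used here. Set against the scanner table, differences between its arrays matched quantile-normalized log2 intensities without background correction, with a median SD within a probe of 0.00198. Its scale and direction were thus found. Each probe is centred on a value that stays unknown: the median over the 6 arrays lies within 0.005 of 0 for 22.9% of probes only. The column medians were −0.003, −0.002 and 0.004 for the controls and −0.001, −0.002 and 0 for the siRNA arrays. This table served as an alternative. The scanning software's version and any image processing are not given in the sources used here.

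Intensities were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3: a normexp model whose negative control mean and spread were inferred from the detection p-values, an offset of 16, and quantile normalization on the log2 scale. The offset shrinks fold changes of dim probes, while the background step enlarges them. The log2 fold change of ACTC1, a dim gene, was −1.65 as processed, −0.997 with an offset of 50 and −0.94 without background correction. Quantile normalization removes any change that moves all genes alike. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, 19548 in all. The file's gene symbols were updated through the synonyms of an NCBI RefSeq gene table (assembly GRCh38.p14, used for names only; no coordinates are given). A current symbol was found for 27032 probes, 4626 were updated through a synonym that pointed to 1 gene, and 12242 kept the file's name. A further 3270 probes had no symbol, 92 were ERCC spike-in probes and 54 had a symbol turned into a calendar date; none of these entered the gene test. Tested as probes with limma, none of them passed the threshold; of those kept, 111 without a symbol, 0 spike-in probes and 2 with a date had an unadjusted p under 0.05. Each gene was represented by its kept probe with the highest mean over the 6 arrays, which gave 14485 genes. Of the genes named by the rule below, 42 had over 1 kept probe, and in 4 another probe had the opposite sign (CIDEA, PCNA, UQCRB and PSMD12). Probes of the same sign also differed in size, as given below for some genes.

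Groups were compared with lmFit and eBayes of limma, siRNA minus control, two-sided, without a replicate block, and p-values were adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. The prior had 5.90 degrees of freedom and the median residual SD of a gene was 0.188 on the log2 scale. The precision is limited by the 3 arrays per group. A gene not above background on any array of a group was given a bound: the other group's mean against the mean of, per array, the higher of the gene's value and the lowest value among probes above background.

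Before the data were examined, 39 gene lists were fixed with 1178 symbols, of which 1168 are on the array, and 38 kept at least 5 measured genes. They cover lipid metabolism, stress, immune, growth and housekeeping programmes and 6 sets of cell type markers. Lists were tested with camera of limma at a preset correlation between genes of 0.01 against all genes tested, with adjustment over the 38 lists. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance without comparing them with other genes. Members were also adjusted over their list alone. The fixed rule for named genes took FASN, the genes past the threshold whose groups do not overlap and which are above background on all arrays of the higher group (at most 12 up and 12 down), and per list up to 4 members past the threshold over all genes or, where none passed, the 2 with the smallest p. Lists past the list threshold were described in full, by the members past the threshold over the list alone. This gave 115 genes beside FASN, of which 1 is not reported here. A further 11 genes past the threshold over other lists alone count as chosen after their values were seen.

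The fit was tested on simulated data with the real arrays' spread for 14485 genes. It called 9.09% of 66 genes changed by 0.5 on the log2 scale, 86.6% of 67 changed by 1 and 100% of 67 changed by 2, with 9 false calls. The list test called a list shifted by 0.4 and 0 others. Simulated genes were drawn independently of each other, while the correlation that camera estimated in the integrated stress response list was 0.52. The simulation thus cannot show how the tests behave among correlated genes. Alternatives fixed before the data were examined were no background correction, an offset of 50, median scaling, no normalization between arrays, the authors' log2 table, no detection filter, a detection p under 0.01 on all 6 arrays, the mean of a gene's probes, an intensity trend with a robust prior, array weights, the replicate number as a block, each array left out in turn, all kept probes tested singly, a test against a 1.2-fold change, and the other list tests. A covariate for array brightness (the log2 of an array's mean signal) and a fit without replicate 3 of both groups, the dimmest array of each, were added after seeing the data.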

Results

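The study measured messenger RNA in THLE 2 cells, an immortalised human liver epithelial line that the labels describe as normal liver cells, on Illumina HumanHT-12 expression beadchips. The question was which genes respond when fatty acid synthase (FASN), the enzyme that builds palmitate from acetyl-CoA and malonyl-CoA, is silenced with siRNA. RNA from 3 samples of cells transfected with FASN siRNA for 48 h was set against RNA from 3 samples of untransfected cells. No time was taken from the labels for the untransfected cells, so whether culture time was matched is not known. Cells given a non-targeting siRNA were not analysed here, so each difference compares transfected with untransfected cells as well as FASN siRNA with none. The labels do not say whether the 3 samples of a group came from separate cultures, and the p-values then measure only the spread between these samples, which may be technical. Between 18577 and 19867 of 47316 probes were above background on an array, and 14485 genes were tested. The mean bead signal per array was 364, 350 and 254 in control replicates 1 to 3 and 269, 234 and 176 in siRNA replicates 1 to 3. The siRNA arrays were thus dimmer by 0.51 on the log2 scale. An exact two-sided permutation test of this gap gave p = 0.2. With 3 arrays per group its smallest possible p is 0.1, so it could not have passed and decides nothing about the gap.

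FASN messenger RNA was 2.12-fold lower after the siRNA, at 47.2% of the control level (95% interval 36.2% to 61.5%, n = 3 per group). The single FASN probe on the array, ILMN_1784871, gave a signal of 3720 ± 399 (SD, n = 3) in untransfected cells and 1184 ± 223 (SD, n = 3) in transfected cells. After normalization, siRNA replicates 1, 2 and 3 stood at 46.3%, 39.1% and 58.0% of the control mean, and all 3 lay below every control array. The log2 fold change was −1.08 (SE 0.17), with a limma p of 9.1e-05 for this target gene taken alone. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. Adjusted over all 14485 genes by limma, the p was 0.0525, and FASN stood at rank 23 by p. Without normalization between arrays the log2 fold change was −1.68, which includes the lower brightness of the siRNA arrays.

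**Figure D1:**
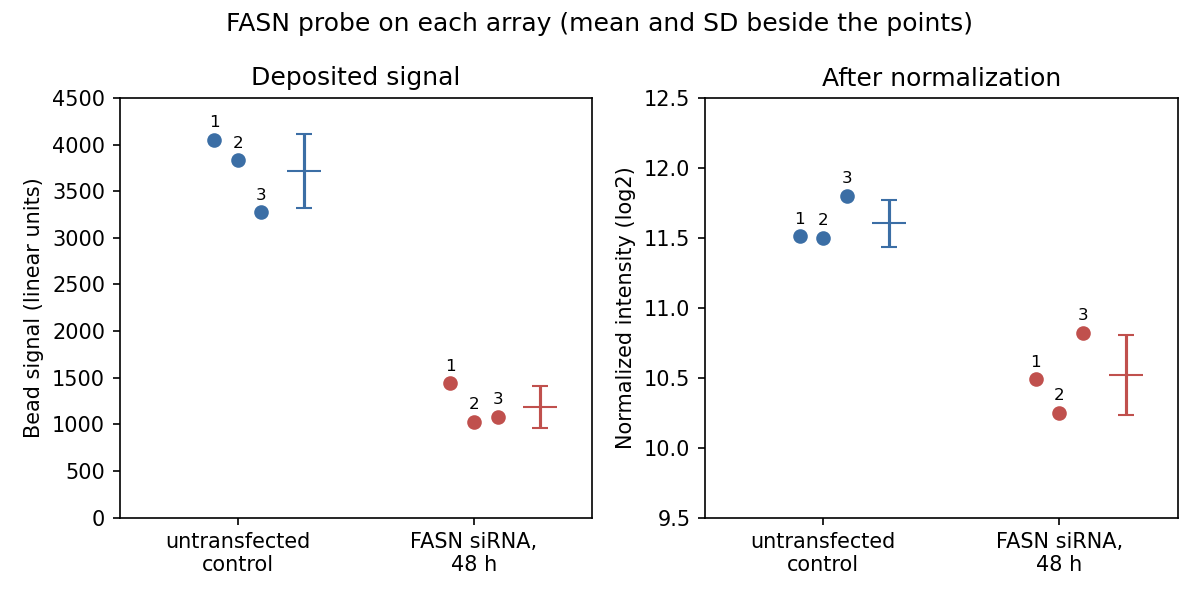
FASN probe signal on each of the 6 arrays, as deposited (left, linear units from 0) and after background correction and quantile normalization (right, log2), with replicate numbers at the points and the mean and SD of the 3 arrays of a group beside them. The 3 siRNA arrays lie below the 3 control arrays in both panels, at 1184 ± 223 against 3720 ± 399 in the left panel.

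Across all genes, 5 changed at an adjusted p under 0.05, 4 higher and 1 lower, and each by over 2-fold. IL24, a cytokine of the interleukin-10 family, rose 4.94-fold (log2 2.31, SE 0.28, limma adjusted p = 0.0299), and its other 2 detected probes were higher by 1.01 and 1.24 on the log2 scale. FOSB, a subunit of the transcription factor AP-1, rose 3.35-fold (log2 1.74, SE 0.16, limma adjusted p = 0.00483). CALB2, which encodes the calcium-binding protein calretinin, rose 3.02-fold (log2 1.59, SE 0.14, limma adjusted p = 0.00473). A transcript that the array file names LOC387763, for which no current symbol was matched, rose 2.36-fold (log2 1.24, SE 0.14, limma adjusted p = 0.0233). ACTC1, which encodes cardiac alpha-actin, fell from 6.54 ± 0.13 to 4.89 ± 0.10 on the log2 scale (SD, n = 3; limma adjusted p = 0.00403). It was not above background on any siRNA array. With the chosen processing this makes it at least 2.85-fold lower, the siRNA arrays being set at the lowest signal above background. Its size depends on the background step: the log2 fold change was −1.65 here, −0.94 without background correction and −1.12 from the authors' log2 values. An unadjusted p under 0.05 was reached by 2499 genes where 724 were expected by chance, 1321 of them higher and 1178 lower. The split of the arrays that sets control replicates 1 and 2 with siRNA replicate 2 against the rest gave 2174 such genes. The 3 values of each group did not overlap for 3355 genes, 23.2% of those tested, where chance gives 10%. The count of 5 fell to 3 without control replicate 1 (LOC387763 and IL24 lost) and to 0 without control replicate 2, and LOC387763 also did not pass without siRNA replicate 1 or siRNA replicate 2. It rose to 277 without control replicate 3 and to 39 without siRNA replicate 3. With array brightness as a covariate 0 genes passed, without replicate 3 of both groups 883 did (both alternatives chosen after seeing the data), and other settings gave from 1 gene to 6371.

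Genes of the integrated stress response and of amino acid supply, which the transcription factor ATF4 drives under amino acid shortage and other stresses, were higher after the siRNA. Of 37 measured members, 35 had a positive log2 fold change, with a median of 0.43. Adjusted over the list alone, 16 rose, 0 fell and 21 did not pass; over all genes none passed. The largest rises were in TRIB3, a pseudokinase induced by this response (2.14-fold, SE 0.26 on the log2 scale), VEGFA, an angiogenic growth factor (2.00-fold, log2 1.00, SE 0.25), DDIT3, which encodes the transcription factor CHOP (1.96-fold, log2 0.97, SE 0.19), and STC2, a secreted glycoprotein (1.92-fold, log2 0.94, SE 0.18). NUPR1, ATF3 and the glutathione-degrading enzyme gene CHAC1 rose by 0.79 each on the log2 scale. The serine and glycine synthesis genes PHGDH (0.53), PSAT1 (0.63) and SHMT2 (0.55) rose too, as did ASNS, the asparagine synthetase gene (0.56), and GPT2 (0.67). So did the amino acid carriers SLC7A1 (0.60), SLC7A5 (0.56) and SLC3A2 (0.53) and the stress sensor SESN2 (0.65). Other detected probes were at 0.24 and 0.23 for SLC3A2, 0.93 for VEGFA and 0.54 for ASNS. The list stood above the other genes by camera with a preset correlation of 0.01 (adjusted p = 9.3e-13) but not with an estimated correlation (adjusted p = 0.385). Fry, which does not compare a list with the other genes, gave an adjusted p of 0.0929. The mean over members, relative to each member's own mean over the 6 arrays, was −0.21, −0.27 and −0.21 in control replicates 1 to 3 and 0.30, 0.44 and −0.05 in siRNA replicates 1 to 3. The count of 16 became 9 without control replicate 2, 28 without siRNA replicate 3 and 30 without replicate 3 of both groups.

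**Figure D2:**
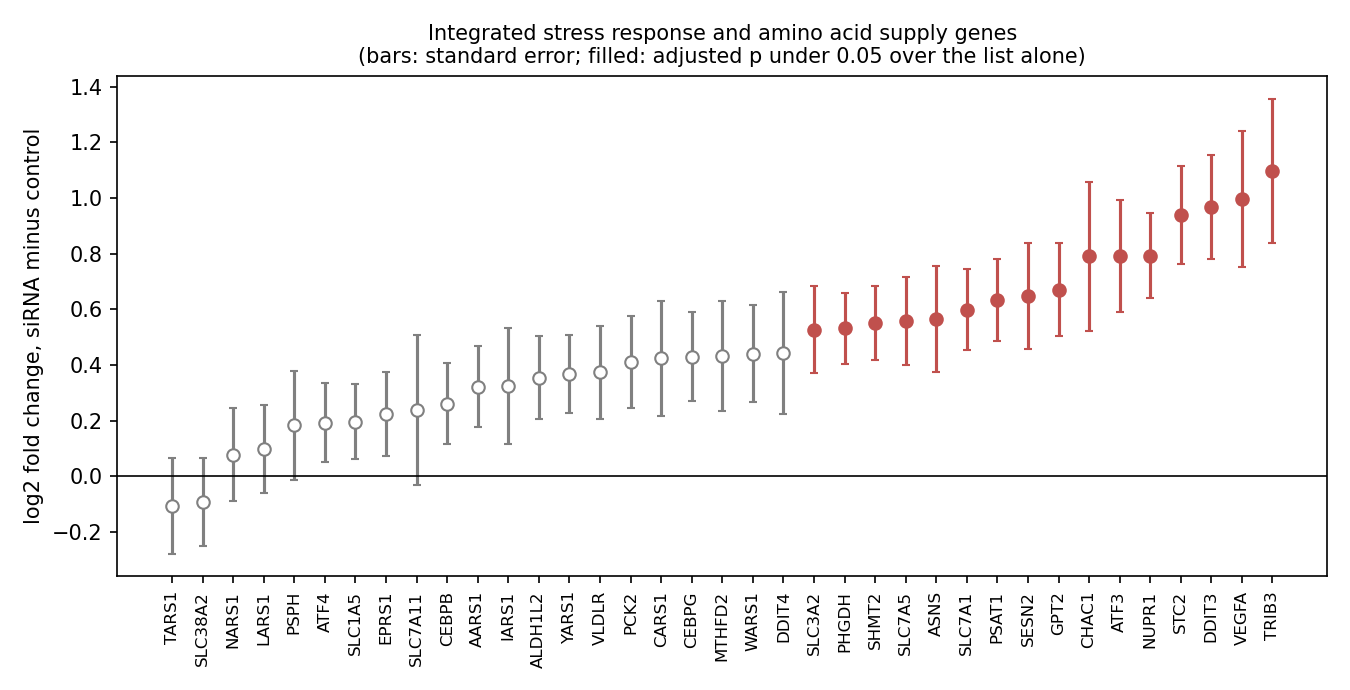
Log2 fold change (siRNA minus control) of the 37 measured genes of the integrated stress response and amino acid supply list, with bars for the standard error and filled points for the 16 genes past an adjusted p of 0.05 over the list alone. All but 2 of the genes lie above 0, and TRIB3, VEGFA, DDIT3 and STC2 are highest.

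By contrast, the list of unfolded protein response genes and chaperones of the endoplasmic reticulum had a median of 0.02 over 28 members and an adjusted p of 0.994 by camera, and none of its members passed, with 2 higher and 0 lower at an unadjusted p under 0.05. HSPA5, which encodes the chaperone BiP, had a log2 fold change of 0.36 (SE 0.15) and SEL1L, a gene of endoplasmic reticulum protein degradation, 0.33 (SE 0.13). The camera direction of this list was down while its median and mean were above 0.

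Inflammatory cytokines and NF-kB targets were higher as a list, with a median of 0.20 over 35 genes and 28 positive. In this list 6 rose, 1 fell and 28 did not pass, adjusted over the list alone; over all genes IL24 alone passed. PTGS2, which encodes the prostaglandin enzyme COX-2, rose 4.14-fold (log2 2.05, SE 0.30) and LCN2, which encodes the iron-carrier binding protein lipocalin 2, rose 3.30-fold (log2 1.72, SE 0.35). CSF3 (1.88-fold), IL1B (1.77-fold) and SAA1 (1.58-fold) rose with IL24, and the chemokine gene CCL2 fell 1.46-fold (log2 −0.54, SE 0.16). Other detected probes were at 0.20 for SAA1, 0.89 for CSF3 and 1.49 for PTGS2 on the log2 scale. Camera with the preset correlation gave an adjusted p of 0.000225 for the list; adjusted p = 0.433 with an estimated correlation, and 0.152 by fry. Relative to all genes the median was 0.19, and it moved to 0.11 without siRNA replicate 2 and to 0.29 without siRNA replicate 3, so its size depends on single arrays. With array brightness as a covariate, an alternative chosen after seeing the data, that median was 0.43. CCL2 no longer passed over the list alone without control replicate 1, control replicate 2, siRNA replicate 1 or siRNA replicate 2, and without replicate 3 of both groups 11 members rose and 2 fell. For the interferon-stimulated genes the median over 46 members was 0.09, the camera adjusted p was 0.572, none of them passed over the list alone, and 1 had an unadjusted p under 0.05. The smallest unadjusted p in that list belonged to the chemokine gene CXCL10, with a log2 fold change of −1.14 (SE 0.48), and next was IFIT2 with −0.35 (SE 0.18). This list depended on single arrays: its score was 0.26, −0.33 and 0.11 in siRNA replicates 1 to 3, and it passed by camera, as higher, without siRNA replicate 2 (median 0.22, adjusted p = 0.000464) and with array weights (0.28, 0.000167).

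Immediate-early genes and feedback genes of MAPK signalling were also higher, with a median of 0.18 over 35 members and 25 positive. Here 6 rose, 0 fell and 29 did not pass, adjusted over the list alone, and over all genes FOSB alone passed. Beside FOSB and ATF3, the transcription factor genes EGR1 (1.71-fold), ETV4 (1.51-fold) and IER2 (1.38-fold) rose, with DUSP5, a phosphatase gene that restrains ERK (1.56-fold, log2 0.64, SE 0.14). The camera adjusted p was 0.000408; adjusted p = 0.385 with an estimated correlation, and 0.0521 by fry. The count of 6 was 3 without control replicate 1 or a detection filter, 1 with median scaling or without control replicate 2, siRNA replicate 1 or siRNA replicate 2, and 9 without replicate 3 of both groups.

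Targets of p53 were higher, with a median of 0.18 over 30 members. Adjusted over the list alone, 8 rose, 0 fell and 22 did not pass, and over all genes none passed. At an unadjusted p under 0.05, 9 were higher and 2 lower. GDF15, a stress-induced cytokine of the TGF-beta family, rose 2.39-fold (log2 1.26, SE 0.25). ZMAT3 rose 1.79-fold, BTG2, an antiproliferative gene, 1.75-fold, and TNFRSF10B, which encodes the death receptor DR5, 1.49-fold. SESN2 (0.65), BAX (0.44), AEN (0.42) and PHLDA3 (0.37), given as log2 fold changes, passed as well. SESN2 is also a member of the integrated stress response list. Other detected probes were at 0.16 for BAX, 0.56 for AEN, 0.56 for ZMAT3, and 0.15 and 0.31 for TNFRSF10B. Camera gave an adjusted p of 0.00198; adjusted p = 0.385 with an estimated correlation, and 0.0125 by fry. The count of 8 was 5 without control replicate 3, siRNA replicate 3 or both, 4 without control replicate 1, and 3 without control replicate 2 or siRNA replicate 1. It was 4 with median scaling or the replicate block, and 0 without normalization between arrays and with array brightness as a covariate, while the camera adjusted p was 0.0124 and 0.0134 in these last settings. Over the list alone 1 member fell without background correction, with an offset of 50, from the authors' log2 values, without a detection filter and with the stricter one. With a trend and robust prior, without control replicate 3 and without replicate 3 of both groups 1 fell too. With array weights 16 rose and 2 fell.

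Genes of mitosis and of the G2 to M transition were lower. The median over 46 members was −0.21, and 40 of them had a negative log2 fold change. Adjusted over the list alone, 7 fell, 0 rose and 39 did not pass; over all genes none passed. CKS2, a partner of cyclin-dependent kinases, fell 1.78-fold (log2 −0.83, SE 0.21), BUB1, a spindle checkpoint kinase gene, 1.58-fold (log2 −0.66, SE 0.13), and the centrosomal kinase gene NEK2 1.56-fold (log2 −0.64, SE 0.15). HMMR (−0.60), DLGAP5 (−0.57), CDCA3 (−0.56) and KIF20A (−0.48), given as log2 fold changes, fell as well. Camera gave an adjusted p of 3.0e-06; adjusted p = 0.385 with an estimated correlation, and 0.0251 by fry. The camera call stood in each fit that left out 1 array. The count of 7 was 14 without replicate 3 of both groups, 13 without control replicate 3, 4 without siRNA replicate 1, and 0 without control replicate 1, control replicate 2, siRNA replicate 2 or siRNA replicate 3. Genes of DNA replication and S phase had a median of −0.03 over 43 members (camera adjusted p = 0.583); none passed, with 2 higher and 1 lower at an unadjusted p under 0.05. E2F2 had a log2 fold change of 0.66 (SE 0.21) and PCNA −0.41 (SE 0.16), with a second PCNA probe at 0.07.

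Genes of oxidative phosphorylation were lower as a list, by small amounts each. The median over 51 members was −0.22 and 47 were negative, while none passed over the list alone or over all genes. An unadjusted p under 0.05 was reached by 10 members, all of them lower. UQCRB of complex III had a log2 fold change of −0.53 (SE 0.16), with another probe of opposite sign, and NDUFC1 of complex I −0.48 (SE 0.15). Camera gave an adjusted p of 9.5e-07; adjusted p = 0.385 with an estimated correlation, and 0.0929 by fry. Over the list alone, 8 members fell without control replicate 3, 10 without replicate 3 of both groups, 31 with array weights and 42 without normalization between arrays. The score was 0.24, 0.11 and −0.02 in control replicates 1 to 3 and −0.13, −0.12 and −0.08 in siRNA replicates 1 to 3. With array brightness as a covariate, an alternative chosen after seeing the data, the median relative to all genes went from −0.22 to −0.11 and the camera adjusted p was 0.0108.

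Smaller downward shifts were seen in other housekeeping groups. No member of these lists passed over the list alone with the chosen processing. With array weights 22 ribosomal protein, 11 proteasome, 9 heat shock and 6 tricarboxylic acid cycle genes fell, while 2, 0, 1 and 2 rose. Without normalization between arrays, where the median of all genes moved by −0.49, 32, 25, 11 and 15 fell. Elsewhere 1 heat shock gene fell without background correction, with an offset of 50 or without a detection filter. Further, 1 ribosomal protein gene fell without control replicate 3 or replicate 3 of both groups. In the tricarboxylic acid cycle list 1 gene rose without siRNA replicate 3, and 1 rose and 1 fell without replicate 3 of both groups. Ribosomal protein genes had a median of −0.13 over 61 members (camera adjusted p = 0.00305, and adjusted p = 0.620 with an estimated correlation, 0.290 by fry), with RPL34 at −0.58 (SE 0.18) and RPL5 at −0.41 (SE 0.13). Proteasome genes had a median of −0.16 over 32 members (0.00909, and adjusted p = 0.477 with an estimated correlation, 0.127 by fry), with PSMB3 at −0.40 (SE 0.14). The proteasome gene with the smallest p, PSMD12, had a log2 fold change of 0.62 (SE 0.19) and another probe of opposite sign. Heat shock genes had a median of −0.15 over 19 members (0.0141, and adjusted p = 0.385 with an estimated correlation, 0.0929 by fry), with the chaperone genes AHSA1 at −0.42 (SE 0.13) and HSPE1 at −0.44 (SE 0.16). The list fixed for the tricarboxylic acid cycle had a median of −0.10 over 26 members (0.0390, and adjusted p = 0.385 with an estimated correlation, 0.0125 by fry). Its member DLD was at −0.45 (SE 0.17), and IDH1, also in the list as fixed, at 0.58 (SE 0.21). With array brightness as a covariate, an alternative chosen after seeing the data, the camera adjusted p was 0.373 for ribosomal proteins, 0.423 for proteasome, 0.423 for heat shock and 0.142 for the tricarboxylic acid cycle. The median relative to all genes then went from −0.14 to −0.02 for ribosomal proteins, from −0.17 to −0.03 for proteasome and from −0.15 to −0.07 for heat shock. For the tricarboxylic acid cycle it grew in size, from −0.10 to −0.16. Without control replicate 1 the adjusted p was 0.0899 for ribosomal proteins and for proteasome and 0.0693 for the tricarboxylic acid cycle. It was 0.0596 for ribosomal proteins without siRNA replicate 1 and 0.0820 for heat shock without siRNA replicate 3. For the tricarboxylic acid cycle it was 0.0670 without control replicate 3, 0.0749 without siRNA replicate 1, 0.0566 without siRNA replicate 2, 0.0719 with array weights and 0.0573 with the replicate block. Without replicate 3 of both groups it was 0.0866 for heat shock and 0.0707 for the tricarboxylic acid cycle. Unadjusted p-values under 0.05 were reached by 1 higher and 3 lower ribosomal protein genes, 1 higher and 1 lower proteasome gene, 0 higher and 4 lower heat shock genes, and 1 higher and 3 lower members of the tricarboxylic acid cycle list. Among all genes 17.3% reached it, a share that the ribosomal protein, proteasome and tricarboxylic acid cycle lists did not reach. For ribosomal proteins another split of the 6 arrays gave a larger mean difference in size, 0.16 against 0.13.

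Genes of autophagy and the lysosome were higher, with a median of 0.23 over 38 members and 31 positive, and none passed over the list alone, with 11 higher and 0 lower at an unadjusted p under 0.05. NPC1, which carries cholesterol out of lysosomes, had a log2 fold change of 0.55 (SE 0.14), and CTSB, the cathepsin B gene, 0.46 (SE 0.13). Camera gave an adjusted p of 0.000167; adjusted p = 0.385 with an estimated correlation, 0.0929 by fry, and 0.107 without normalization between arrays. The call of members depended on the processing: over the list alone, 6 rose without background correction, 5 with an offset of 50, 3 from the authors' log2 values, 6 without a detection filter, 5 with a trend and robust prior, and 24 with 1 lower under array weights. Without control replicate 3, 7 members rose over the list alone, and without replicate 3 of both groups 5 did.

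Targets of sterol-sensing and bile acid-sensing nuclear receptors, with genes of sterol efflux, were higher too. Of 13 members, 4 rose, 0 fell and 9 did not pass, adjusted over the list alone. ABCA1, the pump that exports cholesterol from cells, rose 1.87-fold (log2 0.90, SE 0.17) and APOE, the gene of apolipoprotein E, 1.74-fold (log2 0.80, SE 0.17). MYLIP, which encodes a ligase that marks the LDL receptor for breakdown, rose 1.43-fold, and CYP27A1, the sterol 27-hydroxylase gene, 1.32-fold. Camera gave an adjusted p of 0.0111 for the list; adjusted p = 0.394 with an estimated correlation, 0.0929 by fry, 0.12 with array brightness as a covariate and 0.0568 without normalization between arrays. The median relative to all genes was 0.18, and 0.19 with the brightness covariate. The count of 4 was 2 without control replicate 1, control replicate 2 or siRNA replicate 1. Antigen presentation genes had a median of 0.23 over 23 members, of which ERAP2, an aminopeptidase gene, rose over the list alone (1.81-fold, log2 0.86, SE 0.16) and 22 did not pass. Their camera adjusted p was 0.00261; adjusted p = 0.395 with an estimated correlation, 0.0991 by fry, 0.144 with array brightness as a covariate and 0.0606 without normalization between arrays. With the brightness covariate their median relative to all genes went from 0.23 to 0.13. Without replicate 3 of both groups 3 members rose.

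Mesenchymal and stellate cell markers were lower, with a median of −0.28 over 11 measured members and 10 negative. Of these, 4 fell, 0 rose and 7 did not pass, adjusted over the list alone. The contractile and cytoskeletal genes TAGLN (1.96-fold, log2 −0.97, SE 0.24), MYL9 (1.84-fold, log2 −0.88, SE 0.16) and CNN1 (1.54-fold, log2 −0.63, SE 0.16) fell with VIM, the vimentin gene (1.36-fold, log2 −0.44, SE 0.13). Camera gave an adjusted p of 0.000503; adjusted p = 0.385 with an estimated correlation, and 0.0929 by fry. The count of 4 was 2 without siRNA replicate 1. Among 24 targets of TGF-beta and YAP, 3 fell over the list alone, 0 rose and 21 did not pass, with a median of −0.08. These 3 were ID2 (1.74-fold, log2 −0.80, SE 0.19), ID1 (1.64-fold, log2 −0.71, SE 0.14) and ID3 (1.53-fold, log2 −0.61, SE 0.14), which encode inhibitors of basic helix-loop-helix transcription factors and are textbook targets of BMP signalling. The camera adjusted p of 0.0431 became adjusted p = 0.385 with an estimated correlation and 0.0929 by fry. It was 0.0679 without control replicate 2, 0.127 without control replicate 3, 0.0878 without siRNA replicate 1, 0.0614 without siRNA replicate 2, 0.0707 without replicate 3 of both groups and 0.0540 with the stricter detection filter. Over the list alone, 0 members passed without control replicate 2 and 5 without control replicate 1.

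**Figure D3:**
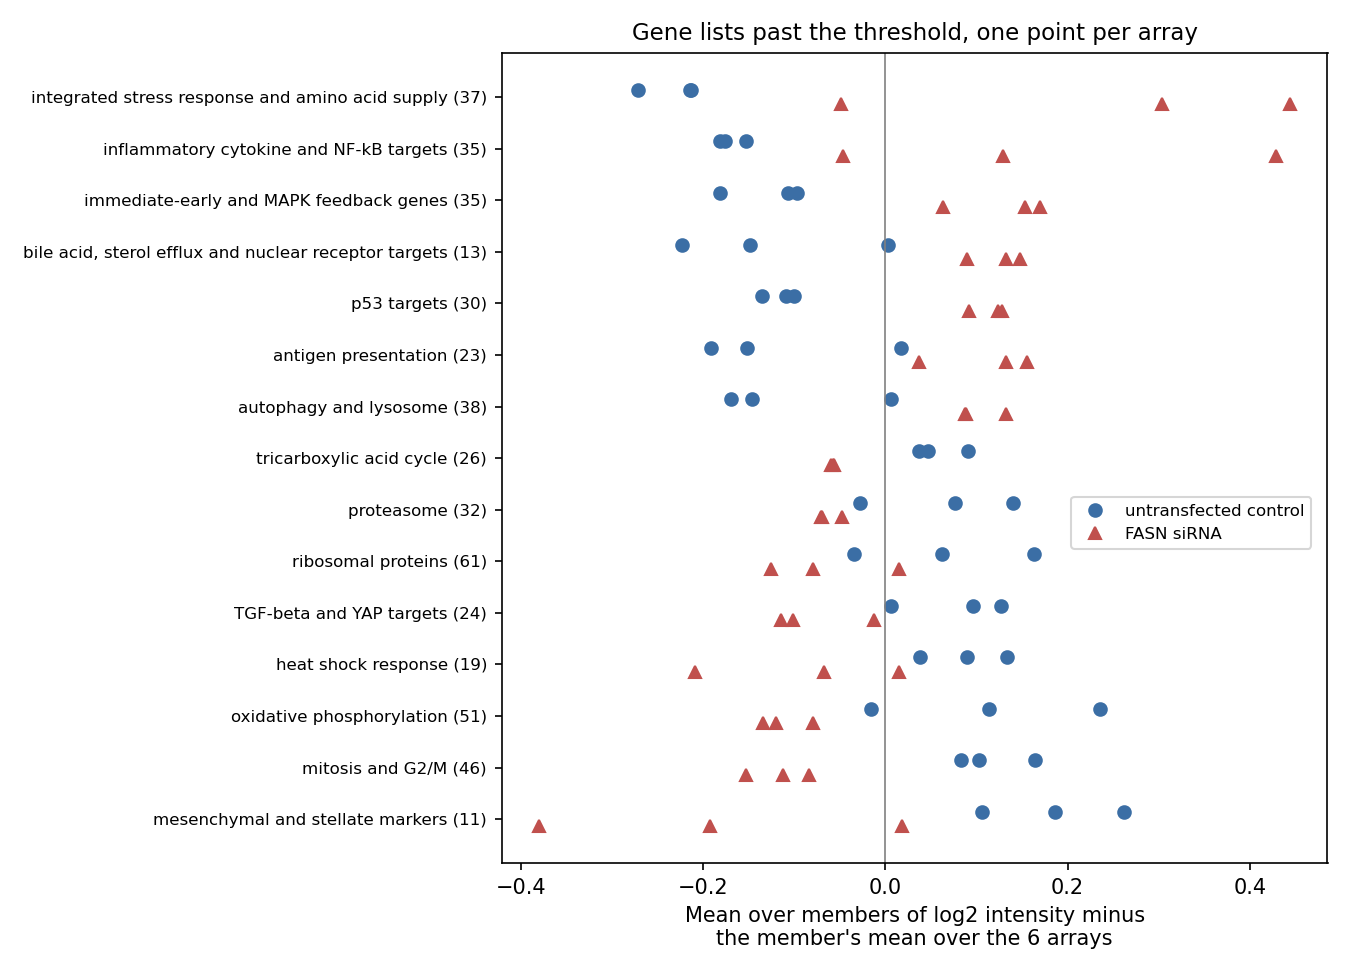
Scores of the 15 gene lists past an adjusted p of 0.05 by camera with a preset correlation, with the number of measured members in brackets and 1 point per array; the horizontal axis is the mean over members of the log2 intensity minus the member's own mean over the 6 arrays. Circles are untransfected controls and triangles are FASN siRNA arrays; the groups do not overlap except for ribosomal proteins, and for the integrated stress response siRNA replicate 3 lies at −0.05, nearest to the controls.

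Of 38 lists tested, 15 passed by camera with the preset correlation, 7 higher and 8 lower. None passed with an estimated correlation, where 3 had an unadjusted p under 0.05, and 3 passed by fry. The median relative to all genes moved most in proportion, when 1 array was left out, for TGF-beta and YAP targets (from −0.08 to −0.15 without control replicate 3). It also moved for heat shock (from −0.15 to −0.24 without control replicate 3 or siRNA replicate 2). Without control replicate 1 it went from −0.14 to −0.06 for ribosomal proteins and from −0.17 to −0.11 for proteasome. For the nuclear receptor list it went from 0.18 to 0.12 without siRNA replicate 1. With array brightness as a covariate, the count over the list alone became 0 for mitosis, 0 for antigen presentation, 1 for the nuclear receptor list, 5 for immediate-early genes and 3 for mesenchymal markers, and 22 for the integrated stress response. Without normalization between arrays, where genes were tested against 0 and the median of all genes lay at −0.49, it became 0 for the integrated stress response, antigen presentation and nuclear receptor lists and 1 for immediate-early genes. In the inflammatory list 3 then rose and 5 fell. The lists that were lower gained calls there: 32 fell for mitosis, 42 for oxidative phosphorylation, 9 for mesenchymal markers and 9 for TGF-beta and YAP targets, beside the housekeeping groups above. With array weights the counts over the list alone were larger in each of the 15 lists, for example 33 higher for the integrated stress response, 31 lower for oxidative phosphorylation, 26 lower and 2 higher for mitosis, and 16 higher for antigen presentation.

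None of the 6 lists of lipid metabolism around the target passed the list test, although the cholesterol list did in 2 alternatives. Among 30 genes of fatty acid synthesis and desaturation the median log2 fold change was 0.01 and the mean −0.02, with a camera direction of down (adjusted p = 0.733). Adjusted over the list alone, 2 fell, 2 rose and 26 did not pass. FASN fell, as did ELOVL6, which lengthens the palmitate that FASN makes (1.53-fold, log2 −0.61, SE 0.14). The transcription factor genes of this pathway rose: MLXIPL, which encodes ChREBP (2.09-fold, log2 1.06, SE 0.19), and SREBF1, which encodes SREBP-1 (1.47-fold, log2 0.55, SE 0.15). Another detected MLXIPL probe was at 0.46 on the log2 scale. ELOVL6 and SREBF1 were named after their values were seen. Genes of cholesterol synthesis and uptake had a median of −0.09 over 24 members (camera adjusted p = 0.258), with a rise over the list alone in HSD17B7 (1.47-fold, log2 0.55, SE 0.13) and a log2 fold change of −0.54 (SE 0.15) in ACAT2. This list passed, as lower, without siRNA replicate 3 (median −0.14, adjusted p = 0.0393) and with array brightness as a covariate (−0.20, 0.0365). Genes of glycerolipid and phospholipid synthesis had a median of 0.00 over 26 members (0.583), of which CHKA, the choline kinase alpha gene (1.60-fold, log2 0.68, SE 0.14), and LPIN2, a phosphatidate phosphatase gene (1.52-fold, log2 0.61, SE 0.15), rose over the list alone.

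For lipid droplets and lipolysis, 1 of 13 members rose over the list alone, 2 fell and 10 did not pass (median 0.11, mean 0.00, camera direction down, adjusted p = 0.941). The droplet coat gene PLIN5 rose 1.47-fold, while CIDEA fell 1.37-fold, with another probe at 0.02 on the log2 scale, and ABHD5, an activator of lipolysis named after its value was seen, fell 1.34-fold. Genes of fatty acid oxidation and ketogenesis had a median of −0.11 over 33 members (camera adjusted p = 0.162); none passed, with 1 higher and 7 lower at an unadjusted p under 0.05. CPT1C had a log2 fold change of 0.54 (SE 0.16) and ACOX2 −0.45 (SE 0.14). Of 11 genes of fatty acid uptake and binding (median 0.03, mean −0.04, camera direction down, adjusted p = 0.733), none passed. FABP5 had a log2 fold change of −0.52 (SE 0.16) and VLDLR 0.37 (SE 0.17).

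The remaining cell type markers gave no list call with all 6 arrays and the chosen processing. Hepatocyte markers had a median of 0.16 over 8 measured members (camera adjusted p = 0.25), with ASGR1, the asialoglycoprotein receptor gene, at 0.44 (SE 0.13) and SERPINA1 at 0.27 (SE 0.14), and none passed. Cholangiocyte and simple epithelial markers had a median of −0.07 over 11 members (0.457), of which KRT7, the keratin 7 gene, fell 1.63-fold over the list alone (log2 −0.70, SE 0.19) and SPP1 had a log2 fold change of 0.61 (SE 0.20). Stratified or basal epithelial markers had a median of −0.26 over 8 members (0.476), with PKP1 at −0.59 (SE 0.19) and S100A2 at 0.55 (SE 0.19), and none passed. Of 6 immune cell markers (median 0.22, camera adjusted p = 0.0747), CD14, the lipopolysaccharide co-receptor gene (1.82-fold, log2 0.86, SE 0.17), and CSF1R (1.45-fold, log2 0.53, SE 0.18) rose over the list alone and 4 did not pass. The list passed, as higher, in 4 of 20 alternatives: with median scaling (adjusted p = 0.0305), without normalization between arrays (0.0124), with the mean of probes (0.0453) and without siRNA replicate 2 (0.0342). The stratified or basal list passed, as lower, with array brightness as a covariate (0.0134). Only 2 endothelial markers were measured, too few for the list test.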

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

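Array brightness as a covariate and leaving out replicate 3 of both groups were chosen after seeing the data. FASN had a negative log2 fold change, from −1.68 to −0.95, and an unadjusted p under 0.05 in all 19 alternative fits. The 5 genes past the threshold, 4 higher and 1 lower and all at least 2-fold, became 62 genes (39 higher, 23 lower), 10 of them at least 2-fold, without background correction. With an offset of 50 they became 49 (31 higher, 18 lower) and 9, with median scaling 13 (12 higher, 1 lower) and 12, and from the authors' log2 values 47 (29 higher, 18 lower) and 12. All 5 genes passed the adjusted threshold in each of these. ACTC1 (log2 −0.937 and −0.997) and LOC387763 (0.908 and 0.956) were under 2-fold without background correction and with an offset of 50. LOC387763 (0.995) was also under 2-fold from the authors' values. Without normalization between arrays there were 955 genes, 541 of them at least 2-fold; the median of all genes then moved by −0.49, and as each gene was tested against 0, the split into 8 higher and 947 lower carries that shift. Median scaling moved that median by 0.04. The count was 1 and 1 with no detection filter, where 30814 genes were tested, 30 and 16 with the stricter filter, 31 and 17 with the mean of probes, and 133 and 33 with a trend and robust prior. With array weights it was 6371 and 67; control replicate 2 then had a weight of 20.6 and no other array one above 2.16. A test against a 1.2-fold change gave 3 genes and all kept probes tested singly gave 6. Leaving out 1 array gave 0 to 277 genes, and 0 to 48 at least 2-fold. With array brightness as a covariate limma called 0 genes, 0 at least 2-fold, with 1774 at an unadjusted p under 0.05. Without replicate 3 of both groups there were 883 and 99. The replicate block gave 71 and 35, but whether the numbers pair the samples is undecided. Deviations of same-numbered samples correlated at −0.109, 0.12 and 0.263, and not every sample correlated best with its own number. Deviations sum to 0 within a group, so these few correlations cannot settle it. The lists past the threshold were 15, and 12 to 18 in the alternative fits, but 0 by camera with an estimated correlation and 3 by fry. The 15 lists kept their direction in 315 of 315 values and passed in 261; the other lists passed in 28 of 481 values, 11 of them of ribosome biogenesis, and had the opposite direction in 38, never past the threshold. Relative to the median of all genes in each fit, named genes had the opposite direction in 0 of 2385 values. Both direction counts were largely fixed in advance. The 15 lists and the named genes were picked for their values on these same arrays, and several alternatives reuse the same fold changes. Neither count thus shows that a direction would hold in new samples. Except where the number of genes tested or the array weights show it, the cause of the differences between settings was not tested. The slide as a block was not run, since the column names give no beadchip. Signal over background limits dim genes: 39.3% to 42.0% of probes were above background on an array.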

Other observations

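Among genes of glycolysis and of the response to hypoxia, of 35 measured members 6 rose and 1 fell over the list alone, and 28 did not pass (median 0.04, camera adjusted p = 0.153). The list passed, as higher, in 3 alternatives: without siRNA replicate 3 (0.00910), without replicate 3 of both groups (0.0380) and with array brightness as a covariate (0.0108). SLC2A3, which encodes the glucose transporter GLUT3, rose 2.19-fold (log2 1.13, SE 0.17), and LOX, the lysyl oxidase gene, fell 1.68-fold (log2 −0.74, SE 0.15). Named after their values were seen, NDRG1 (0.94), CA12 (0.79), PFKFB4 (0.65) and ADM (0.59), given as log2 fold changes, rose with VEGFA. In the extracellular matrix list (36 members, median −0.06, camera adjusted p = 0.991, and 0.0298 with array brightness as a covariate), THBS2, the thrombospondin 2 gene, rose 1.77-fold (log2 0.82, SE 0.14) and THBS1, the thrombospondin 1 gene, fell 2.74-fold (log2 −1.45, SE 0.32). COL6A1 (0.64), MMP9 (0.82) and LAMA3 (0.63) rose over that list alone, named after their values were seen. Among 14 genes of drug and xenobiotic metabolism (median 0.04, camera adjusted p = 0.505), CYP1A1, a target of the aryl hydrocarbon receptor, rose 1.95-fold (log2 0.97, SE 0.17), ALDH1A1, a retinaldehyde dehydrogenase gene, fell 1.81-fold (log2 −0.86, SE 0.17), and NAT1, named after its value was seen, fell 1.53-fold. Of 13 genes of the RNA interference machinery (median 0.12, camera adjusted p = 0.401), AGO2, which encodes the slicing Argonaute protein, rose 1.71-fold over the list alone (log2 0.77, SE 0.20), while XPO5, the exportin for microRNA precursors, had a log2 fold change of 0.46 (SE 0.14) and did not pass.

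A list of 15 histone genes had a median of −0.13 (camera adjusted p = 0.318, and 0.0208 without replicate 3 of both groups), with H2AZ1 at −0.32 (SE 0.13), which did not pass over the list alone. Genes of ribosome biogenesis and MYC targets had a median of −0.12 over 34 members (camera adjusted p = 0.0661), with DKC1 at −0.28 (SE 0.13) and RRS1 at −0.26 (SE 0.12). That list passed, as lower, in 11 of 21 alternatives, with the lowest adjusted p, 0.00342, under median scaling, so its place beside the threshold depends on the processing. NRF2 targets had a median of 0.05 over 27 members (0.191), with ABCC3 at 0.58 (SE 0.15) and PRDX1 at −0.42 (SE 0.13); the list passed, as higher, without control replicate 1 (0.00717), without siRNA replicate 3 (0.00392) and with array brightness as a covariate (1.0e-04). Apoptosis genes had a median of 0.05 over 26 members (0.812), with BIRC2 at −0.47 (SE 0.15) and FADD at −0.32 (SE 0.13). Metallothioneins had a median of −0.10 over 8 members (0.583), with MT1G at −0.31 (SE 0.16) and MT2A at 0.19 (SE 0.14). Widely used reference genes had a median of −0.07 over 16 members (0.915), with GAPDH at −0.37 (SE 0.13) and TFRC at 0.45 (SE 0.15). None of the members of these last 5 lists passed over the list alone, and each p given for a list is camera's adjusted p.

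The tests that count other splits of the samples, and the weighing of transfection itself, were chosen after the results were seen. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 5 genes past the threshold, all at least 2-fold, and the highest of the other splits 0; 1 of the 10 splits reached each count, the real one. An unadjusted p under 0.05 was reached by 2499 genes in the real split and by 2174 with control replicates 1 and 2 and siRNA replicate 2 on one side, the highest of the others. For gene lists the real split gave 15 and the highest of the others 14, with control replicates 1 and 2 and siRNA replicate 3 on one side, and again 1 of the 10 splits reached the real count.

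The higher integrated stress response list was weighed against array brightness, signal level and transfection. The slope of the list's score on brightness within groups, times the brightness gap, predicts a group difference of −0.17 (95% interval −0.65 to 0.30). The difference seen was 0.47, which argues against brightness as its whole cause but does not exclude it. At equal brightness the difference was 0.64, with a 95% interval of −0.0097 to 1.29 that includes 0. Of 10000 random lists matched on mean signal, 0% had a median as high, which argues against signal level, although random lists lack the correlation of a pathway's genes. Transfection itself and loss of FASN cannot be told apart, since no array carries cells given a non-targeting siRNA; the interferon-stimulated genes, which respond to some transfected RNA, had a median of 0.0891. That list passed without siRNA replicate 2, so its value rests on that array and decides nothing about amino acid genes. A response to reduced fatty acid synthesis, the difference the design names, may also be a cause and stays untested.

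For the lower oxidative phosphorylation list the same slope predicts −0.069 (95% interval −0.33 to 0.19) against a difference of −0.22. The interval includes the difference, so brightness and the siRNA cannot be told apart with 6 arrays. Of 10000 matched random lists 0% had a median as low, which argues against signal level, although random lists lack the correlation of a pathway's genes. For the lower mitosis and G2/M list the slope predicts −0.028 (95% interval −0.14 to 0.08) against −0.23, which argues against brightness as its whole cause. Here too 0% of matched random lists had a median as low, with the same limit. Fewer dividing cells after transfection or after FASN loss could each lower these genes, and the design does not separate them.

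The siRNA arrays differed among themselves. Replicate 3, with FASN at 58.0% of the control mean, had a score of −0.05 on the integrated stress response list and −0.05 on the inflammatory list. Replicate 2, with FASN at 39.1%, had 0.44 and 0.43, and replicate 1, at 46.3%, had 0.30 and 0.13. With 3 arrays no relation was tested, and siRNA replicate 3 was also the dimmest array. The order of these FASN levels depends on the normalization. The deposited FASN signals were 1440, 1029 and 1083 in siRNA replicates 1 to 3. Control replicate 3, the dimmest control array, likewise had the highest normalized FASN level of the controls, 114.6% of their mean, and the lowest deposited signal among them, 3277.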
